A study of Eohaustorius estuarius with 16 samples.

How the data were processed

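Whole-body RNA of 8 control and 8 cyfluthrin samples was measured on 16 one-colour arrays, 1 for each sample that the labels name. Per the labels' protocols, total RNA was purified on RNeasy columns, except in one laboratory that is not named, and Cy3-labelled cRNA was made with Agilent's Low Input Quick Amp kit. Per the file headers, the scanner's intensity values were extracted with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes give version 9.1. The intensity columns as deposited hold the processed signal of each spot, background-subtracted and detrended within the array and not scaled between arrays, with the median spot and background signals and flags for background, saturation and outliers. The authors' value table of the series was also read. Its deposited log2 values were set against the scanner files, and were close to the geometric mean of a probe's spots after quantile normalization, centred on the probe's median over the 16 arrays. The correlation with values recomputed in that way was 0.986 for control replicate 4 and between 0.999 and 1 for each other array. The medians of its columns ran from -0.11 to 0.12. Scale and centring are inferred from this comparison, and the direction is that of expression. Other tools of the upstream processing are not given in the sources used here.

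Each array carried 15744 spots, of which 536 control spots were left out. The remaining 15208 spots belonged to 8507 probes, 1 per contig, with 1 spot for 2249 probes, 2 spots for 6208 and 10 or 11 spots for 50. Spots marked as non-uniform or population outliers were left out, and saturated spots were kept. The log2 processed signal was reduced by each array's 75th percentile over non-control spots, and the spots of a probe were averaged. A probe counted as well above background on an array where at least 50% of its spots carried that flag. Contigs well above background on at least 8 of the 16 arrays were tested, a filter blind to group that kept 6852 and left out 1655. The signal over background therefore limits what can be said of the dim contigs.

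Before samples were averaged, all pairs of arrays were compared after quantile normalization over the contigs well above background on all arrays. Cyfluthrin replicates 5 and 6 typically differed by less than the software's error estimate, and were averaged on the log2 scale and counted as 1 sample. The design written before the data were examined had 8 samples in each group, and the fit with the pair counted as 2 samples is printed beside the main one. For fits with a term for slide, position or replicate number, 1 array of the pair stood for it, each in turn.

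Groups were compared with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested contigs and a threshold of 0.05. The files were read with the R package data.table, version 1.17.8, and figures were drawn with python 3.11.15 and matplotlib 3.10.9. Single values per sample were compared by two-sided exact permutation tests over all splits into 8 and 7 samples. The steps were tested on simulated data for the cyfluthrin comparison, drawn for the 6852 contigs with 200 of them changed. Each contig was drawn independently from a normal distribution with its own mean and spread, without differences between arrays. Far fewer contigs were changed than the 2055 called in the real data, so the adjusted threshold was also stricter in the simulation. The recovery and the false calls therefore need not hold for the real data. Of the simulated changes, 22.4% were recovered at 1.5-fold, 56.7% at 2-fold and 92.4% at 4-fold, with 8 false calls among 122. The median standard error of a log2 change in the real data was 0.21.

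The rule for the contigs named was set before the data were examined. Since no probe has a gene name in the files used here, the 2 contigs with the largest rise and the 2 with the largest fall were taken among those past the threshold with at least 7 of 8 arrays of one group on one side of the other group's median. The tests of gene lists and the mean over probes of one gene description could not be made for the same reason.

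The alternatives tried were median scaling, the 75th percentile over contigs well above background on all arrays, quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter, a filter on all arrays, outlier spots kept, the flag for a positive and significant signal in place of well above background, eBayes with trend and robust, array weights, slide, row, column or replicate number in the model, other thresholds, and each array left out in turn. Since the files hold no mean spot signal, normexp was run on the median spot and background signals. Alternatives chosen after the data were seen were the E1A spike-in scaling over 6 of the 10 E1A probes, namely those well above background on all arrays, each slide alone, the pair as 2 samples or left out, and the fit without control replicates 1 and 8 and cyfluthrin replicate 2.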

Results

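Gene expression was measured in whole bodies of Eohaustorius estuarius, a burrowing estuarine amphipod used in sediment toxicity tests. The animals had spent 10 days in sediment spiked with cyfluthrin, a pyrethroid insecticide that acts on the voltage-gated sodium channels of nerve cells, or with solvent as the control. The nominal cyfluthrin concentration was 1.6 µg/kg. The series belongs to a comparison of microarray results between laboratories, and the arrays described here come from laboratory F, which extracted its own RNA from samples that the labels give as 8 control and 8 cyfluthrin whole bodies. Per the labels, each was labelled with Cy3 and hybridised to 1 Agilent array with probes for 8507 contigs, the assembled transcript sequences of this species. The files used here pair no probe with a gene name, so contigs are given by number and the biological lists fixed before the data were examined could not be matched to any probe. The labels do not say whether samples came from separate containers or animals, so the p-values measure only the spread between these samples. The number of arrays limits the precision of each value.

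The agreement between arrays was examined first, since comparability of arrays is the subject of the series. The arrays of cyfluthrin replicates 5 and 6 typically differed by less than the measurement noise that the scanner software estimates. Their typical squared difference was 0.870 times that error estimate, against 3.32 times for the next closest of all pairs, control replicates 2 and 3. The share of contigs outside the 95% range of the error estimate was 9.75% and 29.8% for these pairs. The Pearson correlation of cyfluthrin replicates 5 and 6 across contigs was 0.990. This pair was therefore counted as 1 sample by averaging its log2 values, which left 8 control and 7 cyfluthrin samples. Across the 6852 tested contigs, which are not independent replicates, the median correlation was 0.923 within the control group, 0.915 within the cyfluthrin group and 0.902 between the groups. The lowest values were 0.822, 0.828 and 0.790. The root mean square distance of a sample from the mean of the rest of its group was 0.733 ± 0.197 (SD, n = 8) log2 units in controls and 0.774 ± 0.233 (SD, n = 7) in cyfluthrin samples. This difference was within the spread between samples (two-sided exact permutation test over 6435 splits, p = 0.691, adjusted p = 0.691 over the 4 measures tested in this way).

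Signal quality was compared between the groups in the same way. The share of contigs well above background was 77.2% ± 7.35 (SD, n = 8) in controls and 80.9% ± 1.77 (SD, n = 7) in cyfluthrin samples (exact permutation p = 0.233, adjusted p = 0.311). Control replicate 5 had the highest share of all arrays, 89.4%, and without it the difference grew from 3.65 to 5.38 percentage points (exact permutation p = 0.0309, not adjusted). It shrank to 2.26 points without control replicate 7 and to 2.27 without control replicate 8 (exact permutation p = 0.438 for each, not adjusted). The 75th percentile of the unscaled signal was higher in cyfluthrin samples by 0.70 log2 units, with means of 7.74 ± 0.22 (SD, n = 7) and 7.04 ± 0.45 (SD, n = 8) (exact permutation p = 0.00124, adjusted p = 0.00496). The E1A probes, which detect transcripts that Agilent's protocol adds to the RNA before labelling, were higher by 0.23 log2 units in cyfluthrin samples (9.92 ± 0.17, SD, n = 7, against 9.69 ± 0.23, SD, n = 8). That difference did not pass after adjustment (exact permutation p = 0.0424, adjusted p = 0.0848).

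The first principal component held 36% of the variance between samples and did not separate the groups (exact permutation p = 0.339, adjusted p = 0.339 over the 2 components tested). The second held 18.9%, and all 7 cyfluthrin samples scored above all 8 controls on it (exact permutation p = 0.000311, adjusted p = 0.000622).

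**Figure D1:**
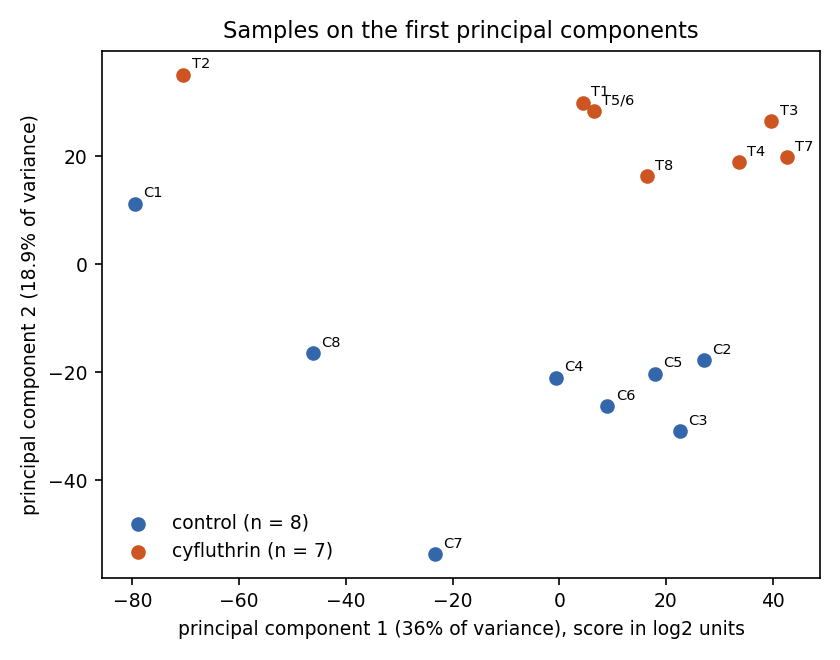
Scores of the 15 samples on the first 2 principal components of the scaled log2 values of the tested contigs, in log2 units; C marks control replicates, T cyfluthrin replicates, and T5/6 the averaged pair. The cyfluthrin samples lie above the controls on the second component, which holds 18.9% of the variance, while control replicates 1 and 8 and cyfluthrin replicate 2 lie far from the others of their groups on the first.

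The effect of cyfluthrin in these animals was the comparison that the design sets for each laboratory. Of the 6852 tested contigs, 2055 (30.0%) changed with an adjusted p below 0.05 in limma, 512 of them upward and 1543 downward. This split depended on the scaling between arrays, with 719 rises and 724 falls under median scaling and 1337 rises and 154 falls under E1A spike-in scaling, an alternative chosen after the data were seen. The median size of a called change was 1.69-fold. At least 2-fold changes were called in 430 contigs, of which 126 rose and 304 fell. The balance turned for large changes, since 37 contigs rose and 10 fell by at least 4-fold, and 24 rose and 0 fell by at least 8-fold. The counts of at least 4-fold changes were 42 rises and 6 falls with median scaling, 46 and 5 with quantile normalization and 61 and 3 with E1A scaling. They were 12 rises and 1 fall with normexp background correction, and 106 and 23 or 94 and 13 with the slide column as a covariate, by the array that stood for the averaged pair. Without cyfluthrin replicate 2, 16 contigs fell by at least 4-fold. The values of the 2 groups did not overlap in 420 contigs (6.13%), 93 higher and 327 lower with cyfluthrin, against the 0.0311% of contigs that chance would give. With replicates 5 and 6 counted as 2 samples, as the design had set out, 2237 contigs were called, 602 upward and 1635 downward. With normexp background correction 3646 were called, 592 upward and 3054 downward.

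**Figure D2:**
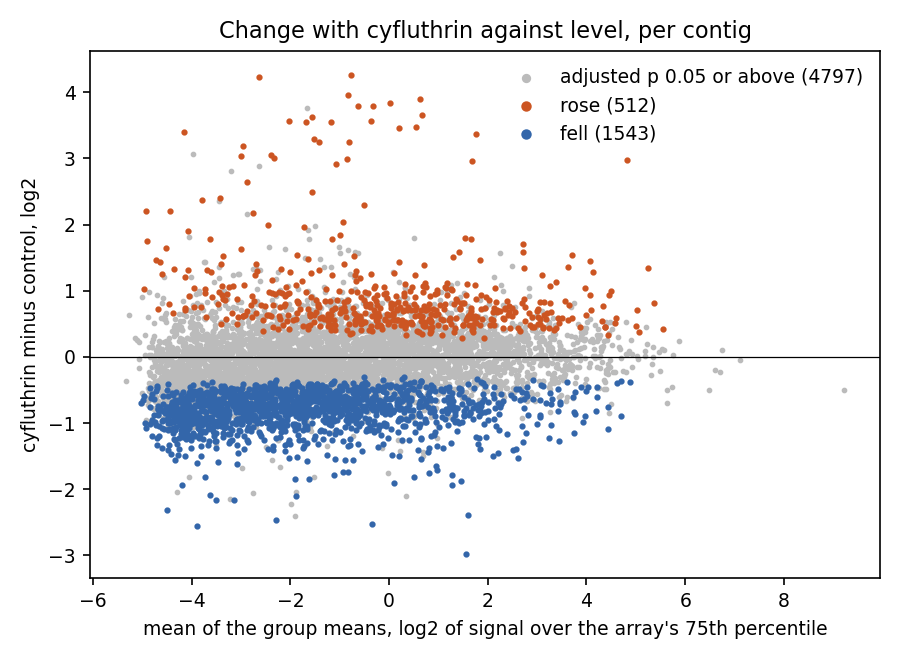
Change with cyfluthrin (cyfluthrin minus control, log2) of each tested contig against its mean scaled log2 level; each point is a contig, orange for the 512 that rose, blue for the 1543 that fell and grey for the rest. With this scaling, by the 75th percentile, falls lie mostly below 2-fold and toward dim contigs, and a separate cloud of contigs lies above 3 on the log2 scale.

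With the 75th-percentile scaling of the processed signal, contig_4879 and contig_4390 rose most among the contigs that met the rule for naming. Both lie among the contigs whose values did not overlap between the groups. The level of contig_4879, as log2 of the signal over the array's 75th percentile, was -2.90 ± 1.08 (SD, n = 8) in controls and 1.37 ± 0.99 (SD, n = 7) in cyfluthrin samples. The rise was 4.27 ± 0.50 (SE) on the log2 scale, or 19.2-fold, with a limma adjusted p of 0.000208. Control values ran from -4.82 to -1.92 and cyfluthrin values from -0.62 to 2.47. This contig was well above background on 6 of the 8 control arrays and on all 8 cyfluthrin arrays. The level of contig_4390 was -4.76 ± 1.06 (SD, n = 8) in controls and -0.52 ± 0.95 (SD, n = 7) with cyfluthrin, a rise of 4.23 ± 0.48 (SE) or 18.8-fold (limma adjusted p = 0.000208). It was well above background on 4 of the 8 control arrays and on all 8 cyfluthrin arrays.

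With the same processing, contig_356 and contig_357 fell most among the contigs that met the rule for naming. The level of contig_356 was 3.04 ± 1.12 (SD, n = 8) in controls and 0.068 ± 0.96 (SD, n = 7) with cyfluthrin. It fell by 2.98 ± 0.50 (SE) on the log2 scale, or 7.87-fold (limma adjusted p = 0.00143), and was well above background on every array. Its control values ran from 1.42 to 4.63 and its cyfluthrin values from -1.24 to 1.21. The level of contig_357 was -2.61 ± 0.81 (SD, n = 8) in controls and -5.17 ± 0.69 (SD, n = 7) with cyfluthrin, so that it fell by 2.56 ± 0.37 (SE) or 5.89-fold (limma adjusted p = 0.000493). It was well above background on all 8 control arrays and on 4 of the 8 cyfluthrin arrays. Control replicate 7, at -0.77, lay far above the other controls for this contig. With normexp background correction, whose offset of 50 draws dim values together, the changes were smaller. They were 2.21 for contig_4879, 1.09 for contig_4390 and -0.98 for contig_357, and each stayed past the threshold. The rise of contig_4390 was then not among the largest, since 12 contigs rose at least 4-fold.

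**Figure D3:**
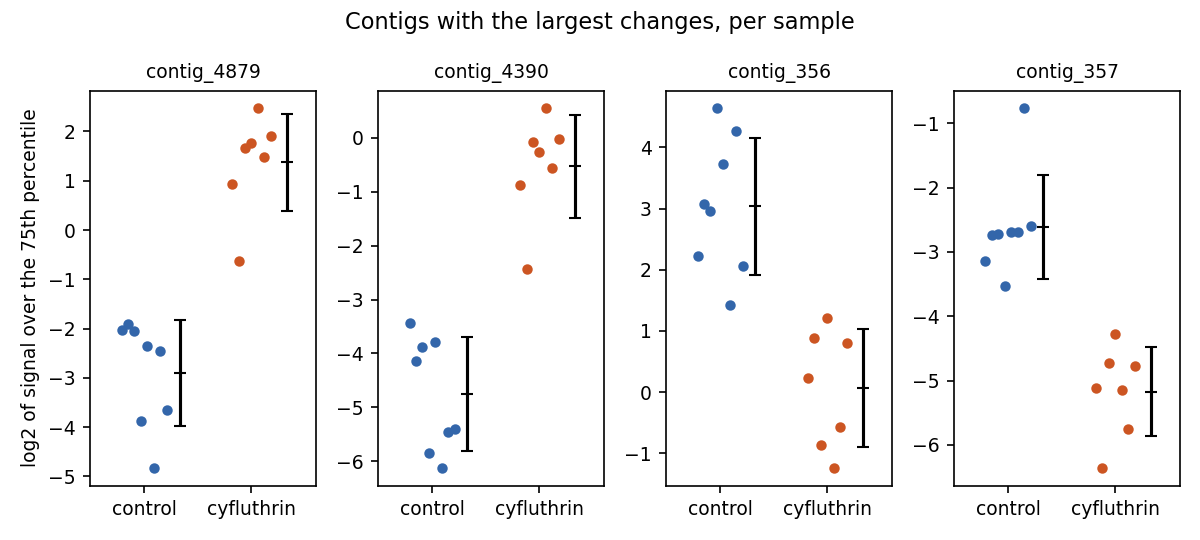
Levels of contig_4879, contig_4390, contig_356 and contig_357 in each sample, as log2 of the signal over the array's 75th percentile; points are samples, with the group mean and SD beside them (8 control and 7 cyfluthrin samples). The groups do not overlap in any of the 4 panels, and each panel has its own vertical scale.

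Well above background on all 8 cyfluthrin arrays and on 0 control arrays were 3 contigs. Each has only a bound on its rise, taken as the cyfluthrin mean over the mean of the higher of its own control value and the lowest signal well above background on each control array. These bounds were at least 2.21-fold, 2.34-fold and 6.68-fold. The limma adjusted p of these contigs, 0.00124, 0.00123 and 0.000252, belong to the change in measured values, and the bounds themselves were not tested. The reverse, all control arrays and no cyfluthrin array, was found for 0 contigs.

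With the 75th-percentile scaling the balance of rises and falls differed by level. In the dimmest 20% of the tested contigs 42 rose and 393 fell, with a median change of -0.41 on the log2 scale over all of these contigs. In the brightest 20% 168 rose and 183 fell, with a median change of 0.043. The median over all tested contigs was -0.16 with the 75th-percentile scaling. With median scaling it was 0.0074. With quantile normalization it was -0.026, and 585 rose and 839 fell. By level there were then 98 rises and 92 falls in the dimmest 20% and 129 rises and 201 falls in the brightest 20%. With scaling to the E1A probes it was 0.31. The balance of rises and falls is therefore relative to the scaling. Under all 5 scalings, which include the 75th percentile over contigs well above background on all arrays, 461 contigs were called to rise and 149 to fall, and 0 were called in opposite directions. Under the 4 scalings without the E1A probes, 461 were called to rise and 563 to fall. Whether the E1A transcripts were added in equal amounts to all samples is not known. Of the 37 contigs that rose at least 4-fold, 35 were called to rise under all 5 scalings, and of the 10 that fell at least 4-fold, 10 were called to fall.

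**Figure D4:**
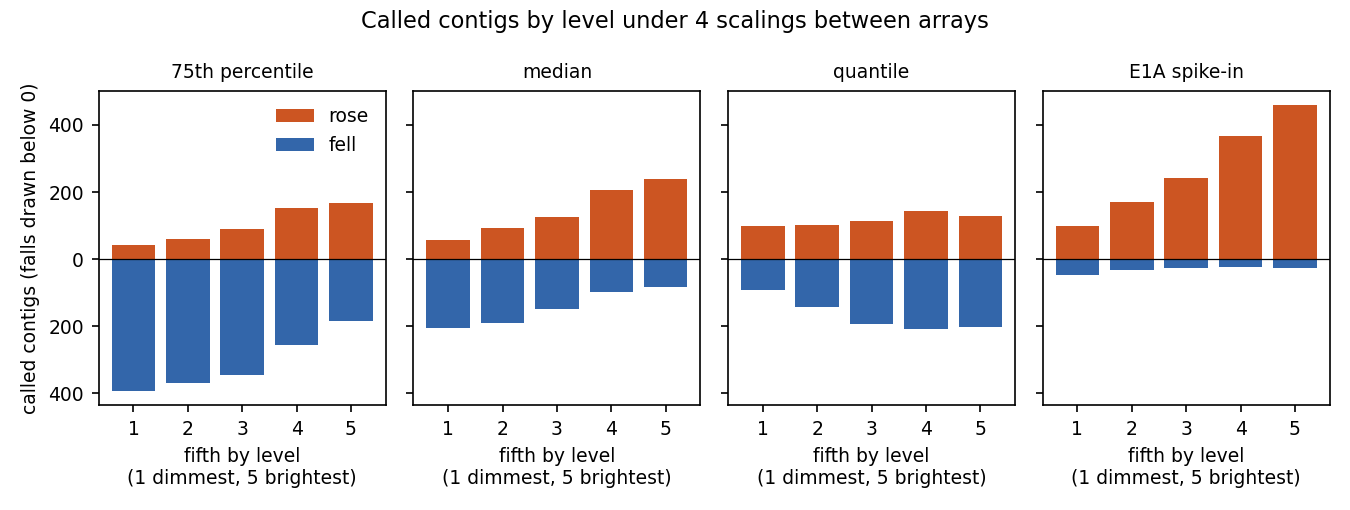
Number of tested contigs called to rise (orange, above 0) and to fall (blue, below 0) with cyfluthrin in 5 classes of equal size ordered by level, under 4 scalings between arrays. In the dimmest class 393 fell and 42 rose with the 75th percentile, 205 fell and 56 rose with the median, 92 fell and 98 rose with quantile normalization, and 48 fell and 99 rose with the E1A spike-in scaling.

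The arrays lay on 2 slides with 4 arrays of each group on each slide. With the slide as a block, and 1 array standing for the averaged pair, 2165 contigs were called with the array of replicate 5 and 1888 with that of replicate 6. On slide 1 alone, with 4 control and 4 cyfluthrin samples, limma called 0 contigs at an adjusted p below 0.05 and 1526 at an unadjusted p below 0.05. On slide 2 alone, with 4 control and 3 cyfluthrin samples, it called 879 contigs, 235 upward and 644 downward, and 2462 at an unadjusted p below 0.05. Of the 879, 97.2% had the same direction on slide 1, against 76.2% of all tested contigs. Past the unadjusted threshold on both slides, 200 contigs rose where 36.6 would be expected from independent lists, and 754 fell where 298 would be expected. In opposite directions there were 3, with 213 expected. Both slides had only cyfluthrin arrays in column 3, and the same scaling was used on both. Agreement above that of independent lists therefore cannot separate cyfluthrin from array position or scaling. Across contigs, which are not independent replicates, the changes on the 2 slides had a Pearson correlation of 0.652 and a Spearman correlation of 0.647. A test of the difference in change between the slides called 0 contigs, and 280 at an unadjusted p below 0.05 where 342.6 would be expected by chance.

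**Figure D5:**
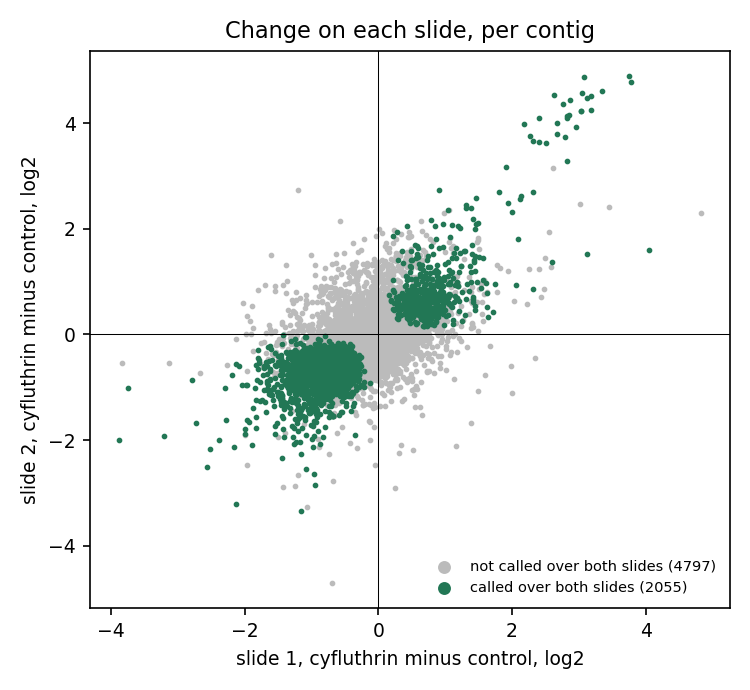
Change with cyfluthrin (cyfluthrin minus control, log2) on slide 1 (4 control and 4 cyfluthrin samples) against slide 2 (4 control and 3 cyfluthrin samples); each point is a tested contig, green for the 2055 called over both slides. The correlation across contigs was 0.652, and the contigs with the largest rises lie in the upper right on both slides.

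On slide 1 contig_4879 rose by 3.75 and contig_4390 by 3.79 on the log2 scale, contig_356 changed by -3.87 and contig_357 by -3.21, each with a limma adjusted p of 0.103. On slide 2 contig_4879 rose by 4.89 (limma adjusted p = 0.0128), contig_4390 rose by 4.77 (0.00948) and contig_357 changed by -1.91 (0.00578). The change of contig_356 on slide 2 was -1.99 (limma adjusted p = 0.0606). The groups were not spread evenly over the columns of the slides, since 4 cyfluthrin arrays and 0 control arrays stood in column 3. With the column as a covariate, 1148 contigs were called with the array of replicate 5 standing for the pair and 753 with that of replicate 6.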

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

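The tests below of control replicate 5, of the alike pair and of the slides were chosen after the result was seen. So were those with E1A scaling and of the share of falls after subtraction. Median scaling was not in the rule set beforehand for the falls among dim contigs. The other tests were fixed before their value was computed.

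Samples were screened for values far from the rest of their group, in 22 sets of values, of which chance would mark about 1 in 20. In 5 sets a sample stood apart. The E1A spike-in signal of cyfluthrin replicates 5 and 6 was 10.29 on the log2 scale, against 9.81 to 9.90 in the other cyfluthrin samples. The 3 dimmest E1A probes averaged 4.34 in control replicate 5, against 1.23 to 1.95 in the other controls. The distance of control replicate 1 from the rest of its group was 1.17 log2 units, against 0.559 to 0.826. In cyfluthrin replicate 2, 233 contigs lay at least 8-fold below the median of the rest of the group, against 1 to 80 in the other cyfluthrin samples. The level of contig_357 was -0.77 in control replicate 7, against -3.53 to -2.59 in the other controls.

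The number of contigs changed by cyfluthrin, 2055, was compared with other splits of the 15 samples. Of 100 splits 1, the real one, gave as many, and the highest of the others gave 156. This argues against chance in the grouping as its source, to a resolution of 1 in 100. The splits cannot tell cyfluthrin from array position or container, which may differ between the groups.

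Falls outnumbered rises among the dimmest contigs, with 393 falls and 42 rises. The raised dim signal of control replicate 5 is not enough to account for it, since without that array 87.5% of that number of falls was called. The scaling between arrays stays open. Of the called contigs in the dimmest 20%, 48.4% fell with quantile normalization, 78.5% with median scaling and 32.7% with E1A scaling. The share with quantile normalization met the bound set beforehand for scaling as the cause. That rule named quantile normalization alone, and median and E1A scaling were weighed beside it because that method equalises the arrays. Normexp background correction gave 1193 falls and 0 rises there, which cannot decide the question. It added an offset of 50 to each spot before scaling. The 75th percentile of the unscaled signal was higher in cyfluthrin samples, so dim contigs near the offset are drawn down there by the processing. Quantile normalization makes the arrays' distributions equal by construction, and no single factor per array changes the gap between dim and bright contigs. The 75th-percentile scaling was kept when the median negative-control signal was subtracted, so falls due to that scaling would remain. With the subtraction 234 contigs fell and 29 rose, 89.0% falls. This argues against background left in dim spots as the whole cause, but does not separate background from scaling. A part of the shift stays open, since the median change of these contigs was then -0.257, between the bounds set beforehand, and so does an effect of cyfluthrin on weakly expressed genes, which was not tested.

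Cyfluthrin replicates 5 and 6 were nearly alike although they lay on different slides. Their typical squared difference, 0.870 times the software's error estimate, is what 1 RNA sample on 2 arrays would give. A chance likeness of 2 separate samples is argued against by the ratio being 26.2% of the lowest among the other pairs. Their shared high E1A signal may point the same way, and the names of their deposited files carry the same sample number. Whether the RNA was extracted once or a specimen was divided was not tested.

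In 3 of the samples over 100 contigs lay at least 8-fold below the rest of the group: 221 in control replicate 1, 137 in control replicate 8 and 233 in cyfluthrin replicate 2. These were largely the same contigs. Control replicate 1 and cyfluthrin replicate 2 shared 183 where 7.52 would be expected from independent lists, and 129 were low in all 3 samples. The slide is argued against, since these samples lie on 2 slides. After scaling, the other contigs of the same level had a median deviation of at most 0.155 and at least 0.133 log2 units in these samples, not a negative one. This argues against a weakness shared by all contigs of that level. The scaling had removed any weakness of a whole array, and the low contigs were left out of that median. Weak hybridization of a whole array therefore cannot be judged from these values. A state of the animals that the labels do not give, such as sex or moult stage, may underlie them and was not tested.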

How the results depend on the processing

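Of 26 alternatives for the number of changed contigs (2055), other than leaving out arrays, 19 stayed within 1.5 times. With normexp background correction 3646 contigs were called, 592 upward and 3054 downward. With the column on the slide as a covariate 1148 or 753 were called, by the array that stood for the averaged pair; column 3 held no control array. Slide 1 alone gave 0 and slide 2 alone 879. The normexp offset can lower scaled dim contigs in cyfluthrin samples, whose 75th percentile was higher. How far this and other causes account for these differences was not tested. With the replicate number as a block, 949 or 974 contigs were called, by the array that stood for the pair. The deviations over all contigs gave no sign of a pairing by number. Those of same-numbered samples correlated between -0.673 and 0.471, and 0 of 8 controls correlated best with their own number. With so few samples, and other differences between them in the same deviations, a pairing cannot be excluded in this way. Leaving out arrays gave 1522 to 2100. Without control replicates 1 and 8 and cyfluthrin replicate 2, 1761 were called.

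The difference in contigs well above background (3.65 percentage points) ranged from 2.26 to 5.38 when arrays were left out, and its unadjusted exact p was below 0.05 only without control replicate 5. With the flag for a positive and significant signal in place of well above background, it was 1.66 percentage points (exact permutation p = 0.271). The difference in spread between the groups (0.042 log2 units, not past the threshold in any alternative) became -0.016 with quantile normalization, -0.035 with normexp and -0.010 over contigs well above background on all arrays, and ranged from -0.047 to 0.12 when arrays were left out. The difference in the 75th percentile ranged from 0.57 to 0.78 when arrays were left out. The 4 named contigs kept their direction in all alternatives in which they were tested, and lost the threshold on slide 1 alone, contig_356 also on slide 2 alone. They were picked for the largest changes in these same samples, so a kept direction was likely beforehand and adds little support. Signal over background kept 1655 contigs out of the tests. The tests of gene lists and the mean over probes of one description were not run.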

Other observations

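The tests below were chosen after the pattern was seen.

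The 37 contigs that rose at least 4-fold also varied together between samples of the same group. The hypothesis of one set of contigs that varies together was tested on their deviations from the group means. Their mean pairwise correlation was 0.4, against a highest value of 0.119 in 1000 random sets of contigs. These sets were matched on level but not on the spread within groups. The values favour contigs that vary together, though a comparison matched on spread was not made. Of the 37, 27 formed 1 cluster with a mean correlation of 0.727 and 5 formed a second, so not all of them belong to 1 set. The clusters were formed from these same correlations, cut at a set level. A high mean within a cluster therefore follows in part from the method. The mean deviation of the cluster of 27 was 1.46 log2 units in control replicate 1 and -1.63 in control replicate 6. It was 0.967 in the averaged cyfluthrin pair and -1.61 in cyfluthrin replicate 2. Whether these contigs are parts of few genes or belong to one response could not be tested without their sequences.

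Probes with consecutive design numbers varied together in 1 of the 3 design sets on the array. In that set the mean correlation of within-group deviations over 592 pairs of consecutive numbers was 0.181, against a highest value of 0.0702 in 1000 shuffled orders. In the others it was 0.0282 over 1457 pairs, with 718 of 1000 shuffles as high, and 0.046 over 389 pairs, with 181 as high. One candidate explanation is that the numbering of that set groups related sequences, so that some called contigs there may not be independent of each other. The sequences were not used here.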
